A study of Arabidopsis thaliana with 15 samples.

How the data were processed

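Fractions enriched for guard cells from Arabidopsis thaliana were hybridised to Agilent arrays with 45220 spots, 1 array per sample and 1 colour (Cy3), per the labels and the file headers. The 15 samples analysed here form 4 groups by their labels: light (4 arrays), darkness (3), 1000 ppm CO2 (4) and 380 ppm CO2 (4). Per the labels, plants grew with 8 h of light and 16 h of darkness and were treated in chambers at 22 °C, 50% relative humidity and 100 µmol of white light per square metre and second, with 400 ppm CO2 in the darkness experiment and 380 ppm as the ambient level of the CO2 experiment.

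Spot intensity was extracted with Agilent Feature Extraction 9.5.3.1, per the file headers, with the background subtracted, spatial trends removed within each array and weak spots replaced by a small positive value. The scanner files deposited for each array hold this processed intensity on a linear scale, the mean and background intensity of each spot, and flags for saturation, spots out of line with their surroundings and a signal well above background. No normalization between arrays is recorded in them. The authors also deposited a series matrix of log2 values for 43803 spots, all of which matched a spot of the scanner files. How these log2 values were made is not given in the sources used here. Each column correlated better with its own array's processed intensity than with any other array's, at a Spearman correlation of at least 0.988. Its correlation with its own array's mean spot intensity was higher still, from 0.9951 to 0.9995. The column medians lay between 8.009 and 8.015. The columns are thus on a log2 scale, run the same way as the intensity and are centred to nearly the same median, while the method of normalization stays unknown. They were used as an alternative only.

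From the processed intensity, log2 values were computed and the 75th percentile of each array over its 43803 spots for plant transcripts was subtracted. Control spots and spots out of line were left out, saturated spots were kept, and spots of the same probe were averaged. Of 43603 probes, 38413 carry a locus code in the files and 5190 do not. Each of the 29030 loci with a probe was represented by its probe with the highest mean over all arrays, and a gene was tested where that probe was well above background on at least 3 arrays of at least 1 group, which left 24404 genes. The files' gene names were updated through a table of the reference assembly TAIR10.1, which names 9605 of the tested genes by a symbol and does not hold 310 of them. The file headers name another genome build, so no coordinates of that table were used. Where genes had several detected probes, 115 of 3569 genes called in darkness and 170 of 1736 called between controls had another probe called in the opposite direction.

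Differences were tested with limma 3.58.1 in R 4.3.3 (tables read with data.table, version 1.17.8), with lmFit and eBayes over all 15 arrays and a mean per group, so that the groups share an estimate of the spread (11 residual and 1.64 prior degrees of freedom). The comparisons were darkness against light, high CO2 against ambient CO2, the difference of these responses, and ambient CO2 against light. P-values were adjusted with the Benjamini-Hochberg method over all genes tested, and genes with an adjusted p under 0.05 are called. Adjusted p-values are limma's unless another tool is named. Where a gene was below background on every array of a group, its fold is a bound: the mean of the brighter group against the mean, over the dimmer group's arrays, of the higher of the lowest signal among probes well above background and the probe's own signal. The same floor was applied to named genes above background on 1 or 2 of 4 arrays, or on 1 of 3, of the dimmer group, and the fold with it is given as at least that value. Fitted differences of dim genes are without the floor. Where the probe's own signal lay above the floor on every array of the dimmer group, the bound equals the fitted difference.

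The comparisons, tests, 26 gene lists and alternatives were fixed before the data were examined. A list of cytosolic ribosomal proteins, taken from the files' descriptions by a rule fixed at the same time, made 27. The lists hold 484 entries for 470 loci, all with a probe, of which 460 were tested, and 23 list symbols were not held by the reference table and are printed under its own symbol. Lists were tested with limma's camera at its preset correlation of 0.01 and adjusted over the 27 lists, with an estimated correlation and fry as alternatives. Fry tests whether the genes of a list move on balance in a direction, without setting them against other genes: it called 25 lists in darkness, 2 in high CO2 (guard cell identity and cuticle), 12 for the difference and 9 between controls. Members were also adjusted over their list alone. Named genes are the 10 largest rises and falls for darkness and for high CO2 and the 5 largest for the other comparisons, among called genes with a symbol whose arrays do not overlap, then up to 4 members of each list with the smallest p, and 12 genes fixed by name (SLAC1, OST1, HT1, CA1, CA4, KAT1, GORK, NCED3, ABI1, CCA1, ASN1 and RBCS1A).

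The tests were checked on simulated data: values for 24404 genes with the residual spread of each gene over all groups, drawn without correlation between genes, and 200 genes changed by 0.5, 1 or 2 on the log2 scale. For darkness 17.9%, 52.2% and 78.8% of these were recovered and 10 of 109 calls were unchanged genes (9.17%). For high CO2 26.9%, 70.1% and 74.2% were recovered, with 7 of 121 calls unchanged (5.79%), and for the controls 26.9%, 64.2% and 87.9%, with 11 of 130 unchanged (8.46%). A list planted in the dark arrays was called and none of the other 27 was, which does not show how often camera errs on genes that are correlated.

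Alternatives were quantile normalization, scaling to the median, normexp background correction with an offset of 50 followed by quantile normalization (a change of background correction and normalization together), the series matrix values, no filter on dim probes, a filter that asked for a signal above background on every array, the mean of all probes of a gene, a fit with only the compared groups, the replicate number as a block, eBayes with trend and robust, array weights, an adjusted p under 0.01, a log2 fold change of at least 1, and leaving out each array in turn. Each group filled its own slide, so slide could not be a block. Splits of the same arrays into groups of the same sizes were counted for the number of genes called, the number of lists called and the genes called in both responses, not for single lists or genes. The precision of each value is limited by the number of arrays and, for dim probes, by the signal over background.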

Results

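Transcript levels were measured in fractions enriched for guard cells, the pair of epidermal cells that border each stomatal pore, from Arabidopsis thaliana plants of the recorded ecotype COL-0 that were 6 to 7 weeks old. Total RNA from each sample was labelled with Cy3 and hybridised to 1 array with 45220 spots. In a first experiment, 4 arrays came from plants kept for 4 h in light and 3 from plants moved from light to darkness. In a second, 4 arrays came from plants exposed for 4 h to 1000 ppm CO2 and 4 from plants left at 380 ppm CO2. Dark replicate 2 was not analysed here. The labels call the replicates biologically independent. They put the dark samples at 2 h of light and 2 h of darkness, whereas the protocol describes 1 h of light and 4 h of darkness, so the length of the dark period is not settled.

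The 75th percentile of the processed signal lay between 2165 and 2270 on the light arrays, 977 and 1336 on the dark arrays, 1419 and 1634 on the high CO2 arrays, and 1211 and 1575 on the ambient CO2 arrays. Between 71.0% and 91.5% of the spots of an array were well above background. Correlations between arrays of a group lay between 0.961 and 0.994. The number of arrays per group, 3 or 4, limits the precision of every difference. Each group filled a slide of its own, and the light slide alone was scanned on day 1, so slide and group cannot be told apart in any comparison. A measure of RNA composition also differed: 10 probes for nuclear ribosomal RNA had a mean log2 level, relative to the 75th percentile of the array, of 0.13 ± 1.27 (SD, n = 4) in light, 4.09 ± 0.18 (n = 3) in darkness, 2.23 ± 1.53 (n = 4) in high CO2 and 3.09 ± 0.54 (n = 4) in ambient CO2. The first principal component of the 24404 genes tested held 52.5% of the variance and the second 16.5%.

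The first comparison, dark against light, asks which transcripts of guard cells respond to a darkness that closes stomata. Genes known to be induced when light and sugar run out rose most. ASN1 (AT3G47340), an asparagine synthetase, was higher in darkness by 9.496 on the log2 scale (SE 0.36, adjusted p = 4.0e-09). Only 2 of the 4 light arrays measured it above background. With the floor for dim arrays it was at least 722-fold higher, the same as its fitted difference. SEN1 (AT4G35770), a marker of dark-induced senescence, rose by 6.77 (SE 0.27) and DIN10 (AT5G20250), a raffinose synthase family member, by 6.20 (SE 0.29). Genes of glucosinolate synthesis were among the largest falls. CYP79F1 (AT1G16410), which starts the core synthesis of glucosinolates from methionine, fell by 6.11 (SE 0.21), and AOP2 (AT4G03060), which modifies their side chain, fell by 5.88 (SE 0.28). At the stomatal pore itself, the anion channel genes SLAC1 and ALMT12 fell by 1.60 (SE 0.16) and 2.49 (SE 0.29), and the inward potassium channel gene AKT1 rose by 1.92 (SE 0.21). Whether the share of guard cells in the dark fractions differed was not tested.

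In limma's fit, 11352 of 24404 genes passed an adjusted p of 0.05, of which 5113 were higher and 6239 lower in darkness, and 1383 of the higher and 2287 of the lower ones changed by at least 1 on the log2 scale. An unadjusted p under 0.05 was reached by 12884 genes. The split depends on the scaling: with the median of each array as its reference in place of the 75th percentile, 7936 genes were higher and 3887 lower, and the median change of all genes moved from -0.11 to 0.12. Small changes are therefore given relative to the 75th percentile. Set against the ambient CO2 arrays, illuminated controls of the other experiment that may also differ in time of sampling, darkness called 12838 genes. Of the 11352 calls, 8513 were also called in the same direction there, 144 were called in the opposite one and the rest were not called. Both comparisons use the same 3 dark arrays, so part of this agreement is built in, and how much was not measured.

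The 10 largest rises with a gene symbol, in genes whose dark and light arrays did not overlap, also took in BBX20 (AT4G39070), a B-box transcription factor of light signalling, at 6.14 (SE 0.35), ERD5 (AT3G30775), the proline dehydrogenase of the mitochondrion, at 5.58 (SE 0.33), the microRNA precursor MIR846 (AT1G61226) at 5.57 (SE 0.92) and ACS11 (AT4G08040), an enzyme of ethylene synthesis. The last was above background on 2 of the 4 light arrays and was at least 40.5-fold higher. The cell wall and sugar genes BXL2 (4.96, SE 0.20), BGAL4 (4.75, SE 0.36) and MIOX2 (4.64, SE 0.55) completed them. The light controls were themselves low for some of these: against the ambient CO2 arrays the difference was 3.84 for ASN1 (adjusted p = 2.3e-06) and 0.74 for MIR846 (adjusted p = 0.511), but 7.35 for SEN1 and 7.43 for DIN10.

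Among the 10 largest falls, NIMIN1 (AT1G02450), which binds the salicylate regulator NPR1, fell by 6.16 (SE 0.50) and was above background on 2 of the 3 dark arrays. BBX30 (AT4G15248), a small B-box protein of light signalling, fell by 5.96 (SE 0.45). The defence regulator gene WRKY38 (AT5G22570) fell by 5.24 (SE 0.78), and LEA4-5 (AT5G06760), of late embryogenesis and drought, fell by 5.04 (SE 0.53). Each of these 3 was above background on 1 of the 3 dark arrays, and with the floor for dim arrays they were at least 62.3-fold, 37.8-fold and 32.9-fold lower. ABCF2 (AT5G09930) was above background on no dark array and was at least 36.7-fold lower (adjusted p = 2.1e-06). IPMI1 (AT3G58990), of the chain elongation that precedes glucosinolate synthesis, fell by 5.19 (SE 0.29), the xyloglucan enzyme gene XTH31 (AT3G44990) by 4.96 (SE 0.26) and the aspartate kinase gene AK3 (AT3G02020) by 4.91 (SE 0.15).

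Of the 26 genes fixed as induced by darkness or starvation, 21 rose, 1 fell and 4 did not pass (22 rose and 1 fell adjusted over the list alone), with a median change of 2.101. Camera gave this list an adjusted p of 1.4e-12, and adjusted p = 0.0521 with an estimated correlation. AT3G15450, of a family linked to aluminium and auxin responses, rose by 4.27 (SE 0.23). Starch and sugar metabolism went the other way, with 19 of 28 genes lower and 2 higher (20 lower and 2 higher adjusted over the list alone) and a median of -0.65 (camera adjusted p = 1.2e-04, adjusted p = 0.497 with an estimated correlation). DPE2, which breaks down maltose in the cytosol, fell by 1.53 (SE 0.12), APL3, a subunit of the enzyme that makes ADP-glucose for starch, by 1.34 (SE 0.13) and the plastid starch phosphorylase gene PHS1 (AT3G29320) by 0.85 (SE 0.08), while the cytosolic invertase gene CINV1 rose by 1.401 (SE 0.10).

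Genes of the pore's ion transport moved in both directions, 5 of 23 higher and 13 lower (7 higher and 13 lower adjusted over the list alone), and camera did not call the list (adjusted p = 0.257). With the median as reference these counts were 8 higher and 9 lower. After normexp with quantile normalization, at 4 higher and 12 lower, camera called the list lower (adjusted p = 0.0471). The vacuolar potassium exchanger gene NHX2 fell by 2.14 (SE 0.10). KAT1, an inward potassium channel of guard cells, changed by -0.53 (adjusted p = 0.0331) and the outward channel GORK by -0.73 (adjusted p = 0.00179). In CO2 and blue-light signalling, 4 of 22 genes rose and 13 fell (4 and 14 adjusted over the list alone, camera adjusted p = 0.258), against 6 and 5 with the median as reference. The carbonic anhydrase genes CA2 (1.14, SE 0.11), CA1 (0.88, SE 0.11) and CA4 (0.53, SE 0.09) and the calcium-dependent kinase gene CPK3 (0.84, SE 0.10) rose. The blue-light receptor gene PHOT2 fell by 1.63 (SE 0.15) and OST1, the kinase that opens SLAC1, by 1.52. HT1, a kinase that keeps stomata open at low CO2, stood at -0.14 (adjusted p = 0.641). Markers of guard cell identity had a median of -0.52, with 2 of 13 genes higher and 6 lower (the same adjusted over the list alone, camera adjusted p = 0.258), against 2 and 3 with the median of each array as reference. The cuticle gene CYP86A2 fell by 1.02 (SE 0.16), the stomatal transcription factor genes MYB60 and FAMA by 0.88 (SE 0.23) and 0.84 (SE 0.18), and the myrosinase gene TGG2 rose by 1.73 (SE 0.38). The mean change was -0.33 for guard cell markers and -0.45 for cuticle markers, against 0.40 for mesophyll and 0.40 for vasculature markers. The mesophyll direction turned with the scaling. Falls of guard cell genes were therefore not told apart from fewer epidermal cells in the dark fractions.

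The response list for abscisic acid and drought had 10 of 15 genes lower and 1 higher (the same adjusted over the list alone), with a median of -1.36 (camera adjusted p = 0.0179, adjusted p = 0.646 with an estimated correlation). COR15B and COR15A, of cold and drought protection, fell by 2.70 (SE 0.37) and 2.04 (SE 0.32), and KIN1 by 1.39 (SE 0.21). The list for the synthesis, breakdown and core signalling of the hormone had 6 of 31 genes higher and 15 lower (7 and 15 adjusted over the list alone) and was not called (camera adjusted p = 0.257). With the median as reference these counts were 9 higher and 10 lower. Its members parted: the receptor genes PYL5 and PYR1 rose by 3.89 (SE 0.28) and 1.77 (SE 0.13). The catabolic enzyme gene CYP707A2 fell by 3.64 (SE 0.23), and the phosphatase genes ABI2 and ABI1 fell by 1.67 (SE 0.16) and 1.16 (SE 0.11). NCED3, the drought-induced step of synthesis, stood at 0.46 (adjusted p = 0.232).

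The auxin-responsive list had 12 of 22 genes lower and 1 higher (the same adjusted over the list alone), with a median of -0.67 (camera adjusted p = 0.0159, adjusted p = 0.646 with an estimated correlation). IAA5 fell by 1.89 (SE 0.23) and SAUR20 by 1.36 (SE 0.14). This call ended against the ambient CO2 arrays (adjusted p = 0.611) and without dark replicate 4 (adjusted p = 0.0613). Flavonoid and anthocyanin synthesis had 9 of 18 genes lower and 0 higher by limma (the same adjusted over the list alone), with a median of -1.01 (camera adjusted p = 0.00382, adjusted p = 0.497 with an estimated correlation). FLS1, flavonol synthase, fell by 3.62 (SE 0.25), F3H by 1.94 (SE 0.17) and PAP1 (AT1G56650), a regulator of anthocyanins that was above background on 2 of the 3 dark arrays, by 2.75 (SE 0.33).

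Light harvesting and photosystem genes were higher in darkness relative to the 75th percentile, 16 of 26 against 1 lower (17 and 1 adjusted over the list alone). This direction turned with the scaling: 2 rose and 6 fell after quantile normalization, 3 and 7 after normexp with quantile normalization, and 3 and 7 in the series matrix values. The list median was 0.51 and turned to -0.04, -0.08 and -0.09 in these. The list was called before these changes (camera adjusted p = 6.5e-05, adjusted p = 0.634 with an estimated correlation). LHCB1.1 (1.01, SE 0.09) and LHCB3 (0.82, SE 0.08) had the smallest p. The Calvin cycle list behaved alike, with 9 of 14 genes higher and 1 lower (the same adjusted over the list alone, camera adjusted p = 0.00791, adjusted p = 0.646 with an estimated correlation) and a median of 0.40 that turned to -0.06, -0.09 and -0.13 under the same scalings. GAPA rose by 0.87 (SE 0.10), RBCS1A by 0.65 (SE 0.13), and TKL1, a transketolase, fell by 0.55 (SE 0.10). Mesophyll markers, which share genes with both lists, rose with them, 9 of 11 against 2 lower (the same adjusted over the list alone, camera adjusted p = 0.00382, adjusted p = 0.646 with an estimated correlation), against 2 and 2 after quantile normalization. Cytosolic ribosomal protein genes also rose more often than they fell, 72 of 195 against 6 (the same adjusted over the list alone, camera adjusted p = 1.4e-06, adjusted p = 0.646 with an estimated correlation), and kept that order under every scaling, from 42 and 5 in the series matrix values to 124 and 2 with the median as reference.

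Photorespiration had 9 of 20 genes higher and 3 lower (the same adjusted over the list alone, camera adjusted p = 0.0302, adjusted p = 0.646 with an estimated correlation), although 7 rose and 7 fell after quantile normalization. BOU rose by 0.77 (SE 0.09) and GGT1 (AT1G23310), a glutamate:glyoxylate aminotransferase, by 0.81 (SE 0.11). Aquaporins had 7 of 17 higher and 1 lower (the same adjusted over the list alone, camera adjusted p = 0.0361, adjusted p = 0.646 with an estimated correlation), against 7 and 3 after quantile normalization, where the median fell from 0.23 to 0.02. They were led by TIP2;1 at 2.46 (SE 0.24) and PIP2;7 at 1.64 (SE 0.17). Wounding and touch genes had 8 of 19 higher and 1 lower (the same adjusted over the list alone, camera adjusted p = 0.0210, adjusted p = 0.646 with an estimated correlation): the touch-induced TCH3 rose by 2.82 (SE 0.40) and CBF3, a cold regulator, fell by 2.19 (SE 0.26). The vasculature markers were called with 2 of 11 higher, XCP2 (0.76) and CESA8 (0.54), and 1 adjusted over the list alone (camera adjusted p = 0.0319, adjusted p = 0.646 with an estimated correlation). With the median as reference 10 of the 11 rose, and 5 after quantile normalization, with or without normexp, and in the series matrix values. After quantile normalization the medians of wounding (0.73 to 0.76) and vasculature (0.42 to 0.46) kept their size, while that of photorespiration fell from 0.29 to 0.08. The calls of photorespiration, aquaporins, wounding and vasculature ended there (adjusted p = 0.698, 0.355, 0.0564 and 0.194). Those of photorespiration, aquaporins and vasculature also ended without light replicate 4 (adjusted p = 0.113, 0.0999 and 0.113), the last 2 without dark replicate 1 (adjusted p = 0.132 and 0.137), and that of wounding without light replicate 2 (adjusted p = 0.0523). In the mean of each list called, all 3 dark arrays lay beyond all 4 light arrays. The same held for many lists that were not called, so it does not set the called lists apart. These were guard cell identity, ion transport, CO2 and blue-light signalling, clock, light signalling, expansins, nitrate assimilation, jasmonate and cuticle.

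Camera did not call the remaining lists. Clock genes had 6 of 25 higher and 9 lower (the same adjusted over the list alone, adjusted p = 0.493), against 8 and 7 with the median as reference: LNK1 fell by 2.65 (SE 0.20), PRR9 by 3.09 (SE 0.38) and CCA1 by 1.79. Light signalling had 7 of 24 higher and 11 lower (8 and 11 adjusted over the list alone, adjusted p = 0.408) and 9 of each with the median as reference, with BBX31 lower by a change of -4.15 (SE 0.28) and the photoreceptor gene PHYA higher by 1.91 (SE 0.14). Expansins and xyloglucan enzymes had 9 of 22 higher and 8 lower (the same adjusted over the list alone, adjusted p = 0.493), from XTH4 at 3.94 (SE 0.30) to EXPA3 at -1.89 (SE 0.14). Salicylate and defence had 2 of 20 higher and 9 lower (the same adjusted over the list alone, adjusted p = 0.254). Jasmonate had 1 of 14 higher and 4 lower (1 and 3 adjusted over the list alone, adjusted p = 0.341), nitrate assimilation 6 of 13 higher and 2 lower (6 and 3 adjusted over the list alone, adjusted p = 0.257), and heat shock 1 of 10 higher and 6 lower (the same adjusted over the list alone, adjusted p = 0.107). Chlorophyll synthesis had 6 of 15 higher and 3 lower (6 and 4 adjusted over the list alone, adjusted p = 0.429), which turned to 1 and 6 after quantile normalization. PORC, which reduces protochlorophyllide in light, fell by 0.98 (SE 0.11). Cuticle and pavement cell markers had 1 of 10 higher and 3 lower (the same adjusted over the list alone, adjusted p = 0.329), CER1, of wax synthesis, falling by 3.43 (SE 0.24), and trichome markers 1 of 5 lower (the same adjusted over the list alone, adjusted p = 0.348).

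**Figure D1:**
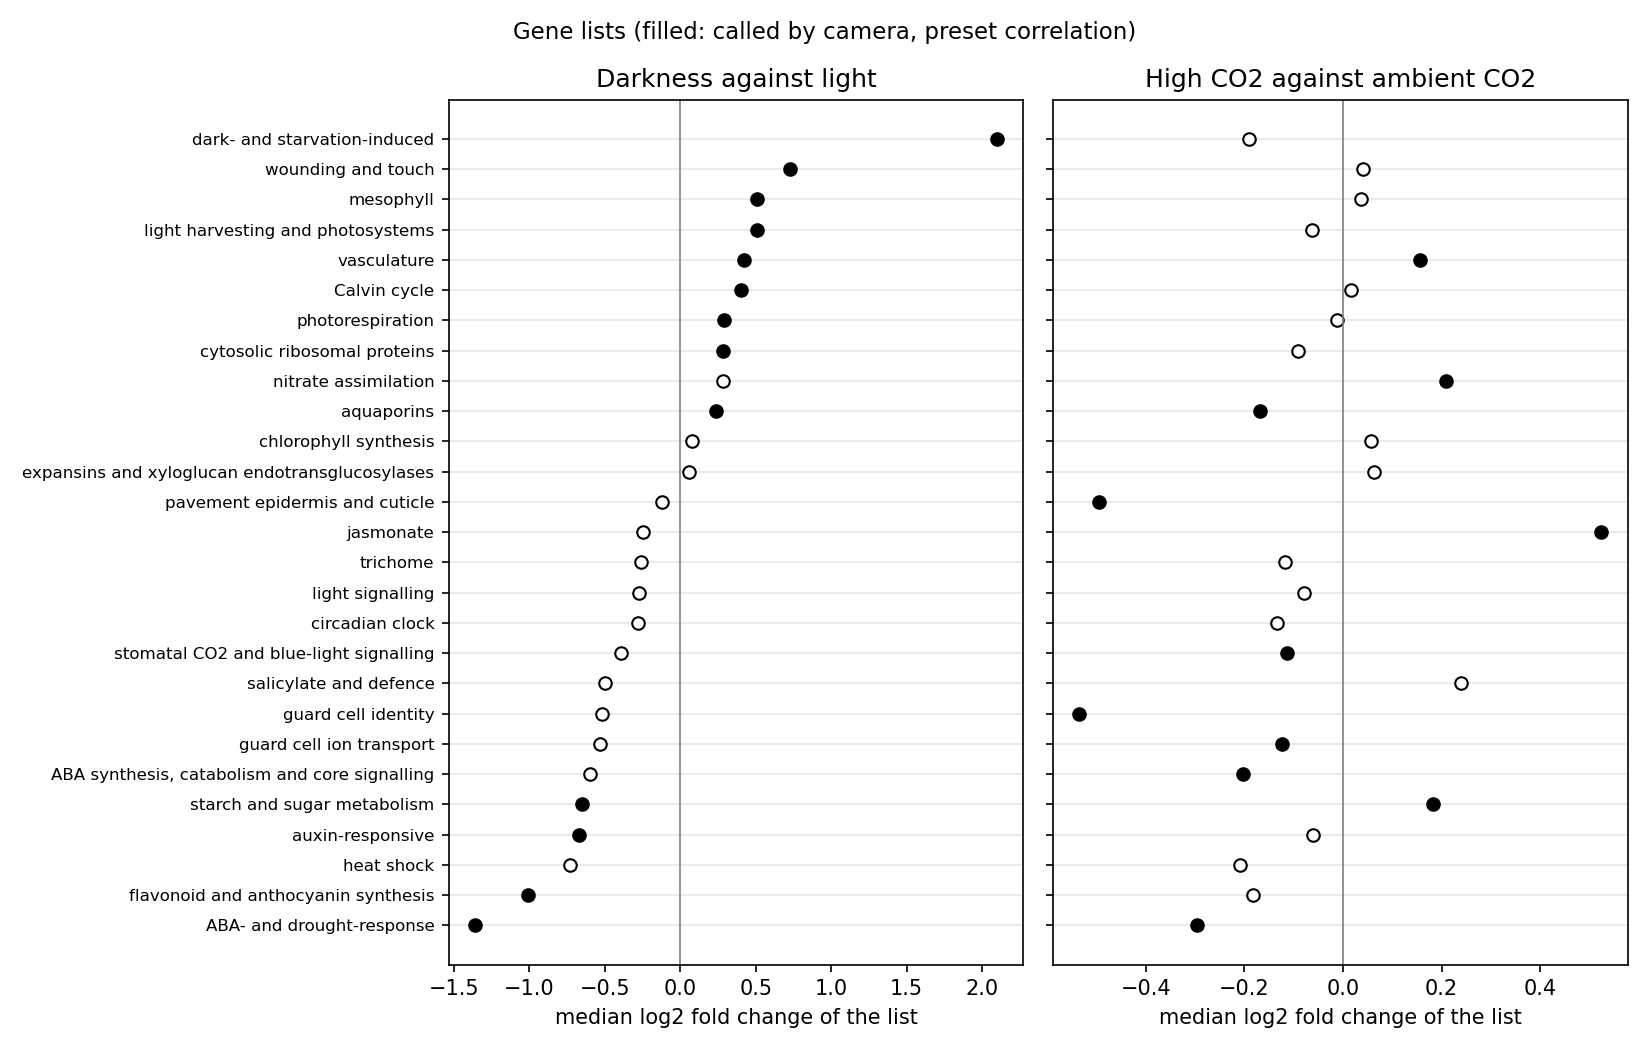
Median log2 fold change of the 27 gene lists (horizontal axis, log2) for darkness against light (left) and high CO2 against ambient CO2 (right), with filled points for lists called by camera with its preset correlation and open points for the others. The list induced by darkness or starvation stood at 2.101 in darkness and the guard cell identity list at -0.53 in high CO2, while the light harvesting and Calvin cycle points in darkness, at 0.51 and 0.40, turned below 0 after quantile normalization.

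The second comparison, high CO2 against ambient CO2, asks which guard cell transcripts respond to a CO2 level that closes stomata in the light. Only few genes passed on their own, and the gene lists moved by fractions of a log2 unit. Markers of guard cells and of the cuticle were lower in high CO2: the guard cell identity list had a median of -0.53 (camera adjusted p = 1.6e-05, adjusted p = 0.253 with an estimated correlation) and the cuticle and pavement cell list one of -0.50 (camera adjusted p = 7.0e-04, adjusted p = 0.211 with an estimated correlation). All 4 high CO2 arrays lay below all 4 ambient arrays in the mean of either list. The guard cell list had nearly the same median in darkness, -0.52, where camera did not call it. The difference of its responses was not called either (camera adjusted p = 0.641). Jasmonate genes were higher, with a median of 0.52 (camera adjusted p = 4.0e-05, adjusted p = 0.253 with an estimated correlation) and 3 of 4 high CO2 arrays above every ambient array. These list calls were thus lost when the correlation between genes was estimated. Between the illuminated controls, ambient CO2 against light, the jasmonate median was 0.74, so a shift of this size also arose without high CO2. The guard cell identity and cuticle lists each stood at -0.08 there and were not called.

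In limma's fit 7 of 24404 genes were called, all lower in high CO2 and all at an adjusted p of 0.0464, and 3122 had an unadjusted p under 0.05. The called genes with a symbol were ZAT (AT2G46800), a vacuolar zinc transporter, which fell by 0.63 (SE 0.09), PAL4 (AT3G10340), a phenylalanine ammonia-lyase, by 0.78 (SE 0.11), and MAPKKK16 (AT4G26890), a kinase of a mitogen-activated cascade, by 1.22 (SE 0.16) and above background on 3 of the 4 high CO2 arrays. The others, named here after their values were seen, were AT1G05894 (-0.69), AT5G14410 (-0.73), AT5G45920 (-1.25) and AT5G66660 (-1.44). The number of calls moved with single arrays and settings. It was 338 without high CO2 replicate 1 and 0 without any other single array of the 2 groups. Only these groups in the fit gave 0, normexp with quantile normalization gave 207 and array weights gave 393.

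No list member passed over all genes in limma, so the following counts are those adjusted over the list alone, and 0 of each list passed over all genes. In guard cell identity 6 of 13 members passed, all lower, among them AT1G22690, a gibberellin-regulated protein gene, at -1.87 (SE 0.44, adjusted p = 0.0973 over all genes), CYP86A2 at -0.63 (SE 0.15) and the myrosinase gene TGG1 at -0.71 (SE 0.18). In the cuticle list 6 of 10 passed, all lower, among them the wax genes CER6 at -0.72 (SE 0.12), CER5 at -0.67 (SE 0.13) and CER1 at -0.86 (SE 0.22). Ion transport had 4 of 23 lower (median -0.12, camera adjusted p = 0.0146, adjusted p = 0.511 with an estimated correlation): NHX1 at -0.66 (SE 0.12), SLAC1 at -0.68 (SE 0.15), the sugar transporter gene STP1 at -1.15 (SE 0.28) and CHX20 at -0.58 (SE 0.17). CO2 and blue-light signalling had 4 of 22 lower and 1 higher (median -0.11, camera adjusted p = 0.0367, adjusted p = 0.511 with an estimated correlation). The lower ones were MPK12, a kinase of the CO2 response, at -1.24 (SE 0.25), BLUS1, a kinase of the blue-light response, at -1.07 (SE 0.23), OST1 at -0.96 (SE 0.22) and AT3G01490 at -0.78 (SE 0.19).

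Jasmonate had 3 of 14 higher, the repressor genes JAZ7 at 1.64 (SE 0.46) and JAZ8 at 1.18 (SE 0.36) and the lipoxygenase gene LOX4 at 0.63 (SE 0.18). Nitrate assimilation had 2 of 13 higher, NIA2, a nitrate reductase, at 0.69 (SE 0.16) and UPM1, of sirohaem synthesis, at 0.46 (SE 0.13), with a median of 0.21 (camera adjusted p = 0.00130, adjusted p = 0.253 with an estimated correlation). Starch and sugar metabolism had 3 of 28 higher and 3 lower, with a median of 0.18 (camera adjusted p = 0.00111, adjusted p = 0.415 with an estimated correlation), from ATSPS4F, a sucrose phosphate synthase, at 0.68 (SE 0.18) to SUS3, a sucrose synthase, at -1.48 (SE 0.28) and the amylase gene BAM1 (AT3G23920) at -1.01 (SE 0.22). Abscisic acid core genes had 2 of 31 lower, the receptor gene PYL2 at -1.19 (SE 0.28) and OST1 (camera adjusted p = 0.00457, adjusted p = 0.511 with an estimated correlation). The response list had 1 of 15 lower, the dehydrin gene RAB18 at -2.19 (SE 0.39; camera adjusted p = 0.00487, adjusted p = 0.550 with an estimated correlation). Aquaporins had 2 of 17 lower, PIP2;5 at -1.25 (SE 0.31, above background on 3 of the 4 high CO2 arrays) and TIP1;1 at -0.58 (SE 0.17; camera adjusted p = 0.00487, adjusted p = 0.511 with an estimated correlation). Vasculature markers were higher as a list with none of 11 passing (median 0.16, camera adjusted p = 0.00632, adjusted p = 0.511 with an estimated correlation), and mesophyll markers had a median of 0.04 and a mean of -0.03 (camera adjusted p = 0.803). In list means, 4 of 4 high CO2 arrays lay beyond every ambient array for nitrate assimilation, CO2 and blue-light signalling and aquaporins, and 3 of 4 for starch, vasculature, ion transport and both abscisic acid lists. The calls of both abscisic acid lists and aquaporins ended without high CO2 replicate 3, and those of ion transport and vasculature without ambient CO2 replicate 2. That of CO2 and blue-light signalling ended without ambient CO2 replicates 1 or 2 (adjusted p = 0.134 and 0.110) or high CO2 replicates 3 or 4 (adjusted p = 0.0694 and 0.109). Between the controls, nitrate assimilation, aquaporins, ion transport and starch had medians of -0.27, -0.47, -0.24 and 0.22, and camera called each. In high CO2 these were 0.21, -0.17, -0.12 and 0.18, so shifts of this size also arose without high CO2. The abscisic acid response list was called at 0.75 between the controls, against -0.30 in high CO2. CO2 and blue-light signalling was called at -0.03.

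The other lists were not called in high CO2. Flavonoid synthesis had 1 of 18 higher and 5 lower, among them F3H at -0.996 (SE 0.15) and C4H at -0.36 (SE 0.08), with a median of -0.18 but a mean of 0.21 (camera adjusted p = 0.355). The list of darkness or starvation had 1 of 26 higher, BT2 at 0.85 (SE 0.18), and a median of -0.19 (adjusted p = 0.321). Light signalling had 1 of 24 lower, ELIP1 at -1.53 (SE 0.36, adjusted p = 0.138 for the list), and light harvesting 1 of 26, LHCB2.3 at -0.65 (SE 0.15, adjusted p = 0.206 for the list). Camera's adjusted p was 0.729 for the clock list, where CCA1 stood at -0.98 (SE 0.27), 0.384 for the Calvin cycle and for wounding, 0.729 for chlorophyll synthesis, photorespiration and trichome markers, 0.597 for auxin and for expansins, 0.0721 for salicylate, 0.0981 for heat shock and 0.138 for ribosomal proteins. In photorespiration, auxin and expansins the median, the mean and the test differed in sign (-0.01, -0.01 and up; -0.06, -0.02 and up; 0.06, -0.05 and up). The fixed genes CA1, CA4, HT1, KAT1, GORK, NCED3, ABI1, ASN1 and RBCS1A were not called here either.

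**Figure D2:**
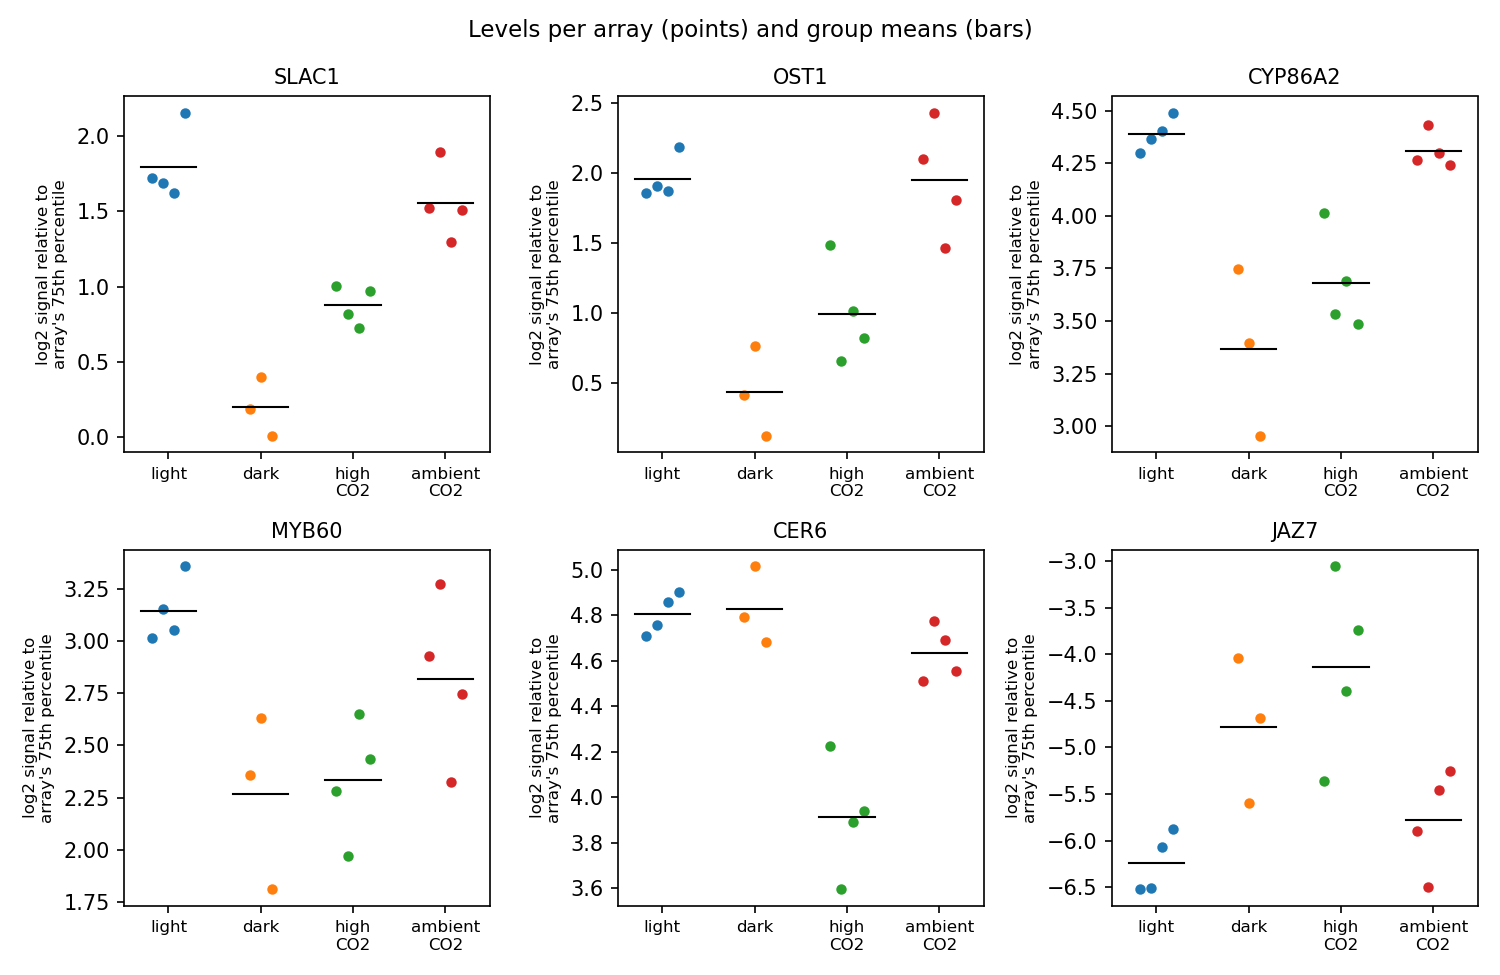
Level of 6 genes on each of the 15 arrays (vertical axis, log2 signal relative to the 75th percentile of the array) in light, darkness, high CO2 and ambient CO2, with points for arrays and bars for group means. For SLAC1, CYP86A2 and CER6 the 4 high CO2 arrays lay below the 4 ambient arrays, for OST1 3 of the 4 did, and SLAC1 fell by 1.60 from light to darkness. For JAZ7 3 of the 4 high CO2 arrays lay above every ambient array. For MYB60 the groups overlapped, with 2.649 on high CO2 replicate 3 and 2.326 on ambient CO2 replicate 3. The light and dark arrays of CER6 overlapped.

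The difference of the responses was tested as an interaction, since the experiments shared no arrays. Among the largest differences, ASN1 rose by 10.17 more in darkness than in high CO2 (SE 0.49), BBX20 by 6.52 (SE 0.48), SEN1 by 6.16 (SE 0.37), and CYP79F1 and AOP2 differed by -6.14 (SE 0.28) and -6.06 (SE 0.39). MIR846 (7.21), ERD5 (6.12), NIMIN1 (-6.03), WRKY38 (-5.86) and BBX30 (-5.69) made up the rest of the 10 largest. The sizes for ASN1 and MIR846 rest on low light controls: against the ambient CO2 arrays these genes rose in darkness by 3.84 and 0.74 (adjusted p = 0.511 for MIR846). Among guard cell genes, STP1 differed by 3.56 (SE 0.41) and NHX2 by -1.98 (SE 0.14). In limma's fit 8334 of 24404 genes differed, 4019 upward and 4315 downward (6754 and 2454 with the median as reference), and 10395 had an unadjusted p under 0.05.

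Across the same lists, the response to darkness lay above that to high CO2 for the list of darkness and starvation (20 of 26 higher, 1 lower; 22 and 1 adjusted over the list alone), which camera called both with its preset correlation (adjusted p = 9.8e-14) and, alone among the 27, with an estimated one (adjusted p = 0.0382). Camera with the preset correlation called 10 lists. Starch and sugar metabolism (18 of 28 lower, 1 higher; 20 and 1 adjusted over the list alone), auxin (11 of 22 lower, 1 higher; the same), flavonoids (7 of 18 lower; 9 lower and 1 higher) and jasmonate (6 of 14 lower; the same) lay lower, at camera adjusted p = 3.4e-06, 0.00709, 0.00709 and 0.0309, and at adjusted p = 0.315, 0.848, 0.560 and 0.844 with an estimated correlation. Aquaporins (6 of 17 higher; the same), ribosomal proteins (65 of 195 higher, 4 lower; 67 and 4), light harvesting (15 of 26 higher; 17), the Calvin cycle (6 of 14 higher, 1 lower; 8 and 1) and mesophyll markers (7 of 11 higher, 1 lower; 8 and 1) lay higher. Their camera adjusted p were 0.00445, 2.3e-06, 2.1e-05, 0.0328 and 0.00673, and adjusted p = 0.631, 0.848, 0.560, 0.848 and 0.844 with an estimated correlation. After quantile normalization the direction of light harvesting, the Calvin cycle and mesophyll markers turned, with adjusted p = 0.946, 0.505 and 0.889, and the call of aquaporins ended (adjusted p = 0.0946).

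How many genes darkness and high CO2 moved in common depended on how many were called in high CO2. Of the 7 genes that fell in high CO2, 3 also fell in darkness, where chance overlap of independent lists gives 1.79 (two-sided Fisher's exact p = 0.382 for 6239 and 7 of 24404 genes), and 2 rose. Settings that called more genes in high CO2 shared more than independent lists give: 84 lower and 16 higher after normexp with quantile normalization (34.3 and 9.48 expected), 42 and 6 in the series matrix values (14.7 and 2.66), 82 and 14 with a signal above background on every array (45.2 and 8.99) and 166 and 27 without high CO2 replicate 1 (70.6 and 12.3). In these, 33, 8, 32 and 56 genes moved in opposite directions, where independent lists give 43.7, 16.7, 50.1 and 72.9. Across genes, which are not independent replicates, the log2 fold changes of both responses correlated with Pearson's r = 0.105 and Spearman's rho = 0.0904, and 52.1% had the same sign. Leaving out 1 array moved Pearson's r from 0.0414 (without light replicate 4) to 0.153 (without ambient CO2 replicate 2). SLAC1 and OST1 lay lower in both, while STP1 was higher in darkness (2.41) and at -1.15 in high CO2. In high CO2 these genes passed only when adjusted over their lists alone, not over all genes.

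The illuminated controls, ambient CO2 against light, differ by slide, experiment and CO2 level (380 against 400 ppm). The time of sampling may differ as well: the light arrays are labelled with 4 h of light, while the CO2 protocol has 1 h of light before 4 h of treatment. Their comparison shows how far such differences reach together. Some genes were bright in 1 control group and near background in the other. HR4 (AT3G50480), a homologue of a mildew resistance gene, was at least 1168-fold higher at ambient CO2 (adjusted p = 1.4e-07) and EXO84B (AT5G49830), an exocyst subunit, at least 393-fold (adjusted p = 2.3e-09), each above background on 1 of the 4 light arrays. AT14A (AT3G28290), above background on 3, was higher by 8.40 (SE 0.52). HSD3 (AT3G47360) and SEN2 (AT5G60230) were above background on no light array and were at least 122-fold and 97.9-fold higher (adjusted p = 3.2e-08 and 7.7e-08). FER (AT3G51550), a receptor kinase, was lower by a change of -5.86 (SE 0.17), although another of its probes was called the other way, DR4 (AT1G73330) by -5.65 (SE 0.43), PXMT1 by -3.03 (SE 1.03) and G6PD4 by -2.94 (SE 0.10), and AGP11 (AT3G01700), on no ambient array above background, was at least 10.3-fold lower.

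**Figure D3:**
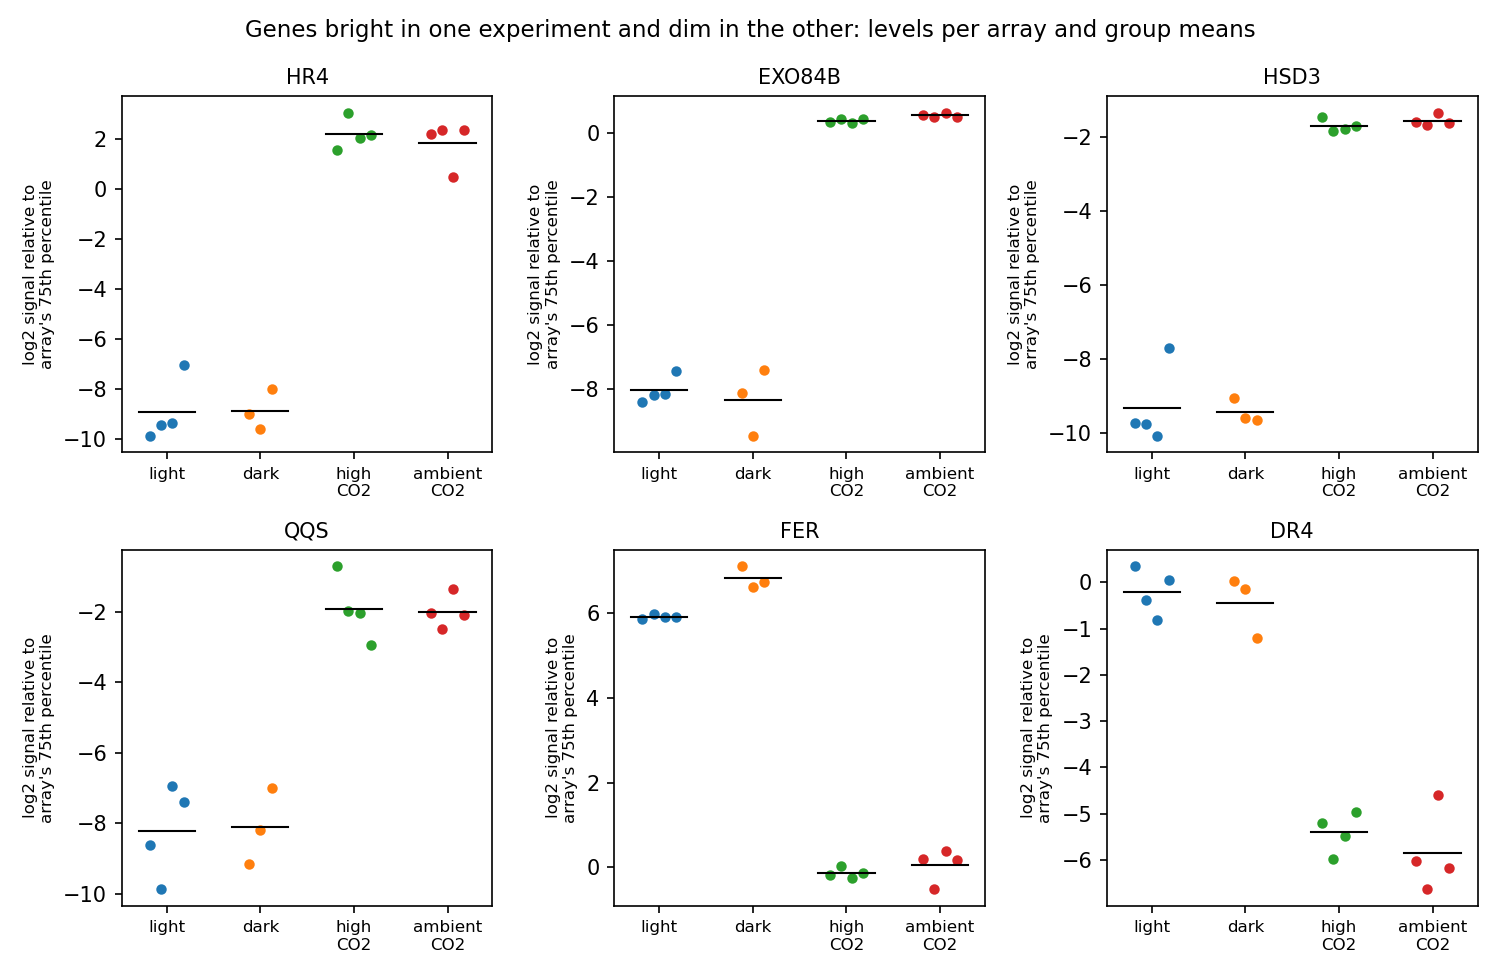
Level of 6 genes on each of the 15 arrays (vertical axis, log2 signal relative to the 75th percentile of the array), with points for arrays and bars for group means. HR4, EXO84B, HSD3 and QQS were bright in high and ambient CO2 and near background in light and darkness, and FER and DR4 were brighter in light and darkness.

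In limma's fit 5630 of 24404 genes differed between the controls, 3545 higher and 2085 lower at ambient CO2 (5357 and 1543 with the median as reference), 1456 of them by at least 1 on the log2 scale, and 9313 had an unadjusted p under 0.05. Without light replicate 3 the count was 3518, and with array weights 11361. Camera called 13 lists with its preset correlation and 0 with an estimated one, and fry called 9. Jasmonate (8 of 14 higher; the same adjusted over the list alone), abscisic acid and drought response (5 of 15 higher; 7), flavonoids (7 of 18 higher, 1 lower; 9 and 1) and starch (7 of 28 higher; 8) lay higher, at camera adjusted p = 0.0362, 0.00552, 0.0325 and 0.0362, each with adjusted p = 0.594 with an estimated correlation. With a signal above background on every array the flavonoid call ended (camera adjusted p = 0.738). The mean of all probes ended those of starch and jasmonate (camera adjusted p = 0.199 and 0.0523). PAP1 was 17.1-fold higher (log2 SE 0.30), the starch-degrading BAM5 by 2.91 (SE 0.29) and LTI30, a dehydrin, by 2.84 (SE 0.41). Nitrate assimilation (5 of 13 lower), aquaporins (7 of 17 lower), auxin (9 of 22 lower, 2 higher; 10 and 2), expansins (7 of 22 lower, 2 higher), chlorophyll synthesis (4 of 15 lower), ion transport (4 of 23 lower), photorespiration (4 of 20 lower), the Calvin cycle (2 of 14 lower) and CO2 and blue-light signalling (4 of 22 lower, 1 higher) lay lower, with camera adjusted p from 0.00134 to 0.0468 and the same counts adjusted over the list alone where none is given, and with adjusted p from 0.583 to 0.628 with an estimated correlation. Nuclear ribosomal RNA probes stood at 3.09 in ambient CO2 against 0.13 in light.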

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

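The tests of scan day, of neighbouring genes, of the side taken by light replicate 4 and of fewer guard cells or fewer epidermal cells in the high CO2 fractions were chosen only after the result was seen.

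The darkness comparison called 11352 genes, and chance is argued against: among the 35 splits of its 7 arrays into 3 and 4, only the real one (1) reached that number, with 4971 as the highest other. Chance is likewise argued against for the 5630 genes between the controls (1 of 35, highest other 1902). The smallest share that 35 splits can give is 1 of 35. In high CO2 the real split also stood alone with its 7 genes (1 of 35, highest other 1). These calls were fragile: each had an adjusted p of 0.0464, and 0 genes were called with the replicate block or with only the compared groups. Of 100 splits for the difference, 2 reached its 8334 genes. A split that kept dark and light arrays apart and mixed the CO2 arrays reached 8422. This count thus follows the structure that darkness gives the arrays and does not test the CO2 grouping. Since each group filled its own slide, no split can tell treatment from slide. For the 3 genes that fell in both responses the splits decide nothing (1 of 100, highest other 0): no other split called more than 1 gene in high CO2, so none could have reached 3. Chance cannot be excluded for how many gene lists camera called. In darkness 6 of 35 splits called at least the real 13 (highest other 18) and in high CO2 17 of 35 at least 11 (highest other 16). For the difference 35 of 100 called at least 10 (highest other 19) and between the controls 4 of 35 at least 13 (highest other 14).

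A total of 56 genes (0.2295% of those tested) lay at least 3 log2 units apart between the nearest arrays of both experiments. Of these, 52 were brighter in the CO2 experiment and 4, FER, DR4, AT1G11370 and AT3G45095, in the light and dark arrays. For genes with another detected probe, the other probes argue against sequence variants under single probes as a general explanation. Of these 21 probes, 76.19% (16) differed by at least 2 the same way. FER is an exception, since another of its probes was called the other way between the controls. Genes without another detected probe are not covered by this test. The light slide of scan day 1 alone parted 1 gene from the other slides, which argues against scan day. Slides in general cannot be told apart from the experiments: the dark slide alone parted 66 genes, and the bound written for that test overlooked that this slide alone carries the darkness treatment. Of the 56 genes, 4 pairs were neighbours on a chromosome against a mean of 0.1252 and a highest of 3 in 10000 random draws of tested genes (permutation p = 1e-04, the smallest these draws can give), so plant lots that differ in gene content may be a candidate explanation, with copies that share probe sequence and inherited silencing left untested.

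Light replicate 4 stood apart from the other light arrays. It had 91.5% of spots well above background, against 79.7% or less on the others (gap over range 0.84), a mean correlation of 0.971 with its group (0.96) and a nuclear ribosomal RNA level of -1.77 (0.896), and over all genes its highest correlation was 0.9768 with a CO2 array and 0.9741 with another light array. A swapped sample is argued against, since on 92.96% of 71 genes that part the experiments, chosen without it, it lay with the light and dark arrays. Low ribosomal RNA signal stays open. The departures of high CO2 replicate 2, the lowest of its group in that signal, correlated with those of light replicate 4 at -0.4331 across genes, but the bound written for that test was wrong, since a single array of another group excludes nothing. For its nearness to the CO2 arrays, a difference in dim spots may be a candidate explanation. Among 15789 bright genes its highest correlation was 0.9865 with another light array and 0.961 with a CO2 array. The lowest among the other 3 light arrays was 0.9796. A highest value set against a lowest cannot show whether it matched its group there as well as they did.

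The markers of guard cells and of the cuticle lay lower in high CO2 together. Fewer guard cells among other epidermal cells stay open. The cuticle and pavement cell score moved by -0.434 (spread between arrays 0.1037), but how far guard cells themselves express these genes was not measured. The guard cell list itself holds a cuticle gene, CYP86A2. Ambient CO2 replicate 3 alone does not carry the shift, since the guard cell list had a camera adjusted p of 7.722e-08 without it. Fewer epidermal cells of any kind in the fraction cannot be told apart from a response of the cells: mesophyll and vasculature scores differed in shift by -0.243 (spread 0.1954), but the mesophyll score starts from so high a level, 6.508 in ambient CO2, that a small share would be hidden. The calls of these lists ended with an estimated correlation (adjusted p = 0.253 and 0.211). In darkness the guard cell and cuticle scores moved by -0.333 and -0.449, and the mesophyll and vasculature scores by 0.4 and 0.403. The trichome score moved by -0.466. A change in the cells of the dark fractions was not tested and cannot be told apart from a response of the cells.

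Single arrays that lay far from the rest of their group were found by the gap to the nearest array over the range, with Dixon's bound for 4 arrays, which chance passes in about 1 of 20 groups. For named genes 11 of 199 pairs of gene and group passed it. These were BGAL4 (0.91), OST1 (0.847), ABI2 (0.887), HSD3 (0.858) and SEN2 (0.901), each highest in light replicate 4, FLS1 (0.884) and EXPA3 (0.853), highest in light replicate 2, and APL3 (0.857), lowest in light replicate 3. The others were LHCB2.3 (0.875), highest in high CO2 replicate 1, HR4 (0.915), lowest in ambient CO2 replicate 3, and G6PD4 (0.833), lowest in ambient CO2 replicate 1. For list means 8 of 81 pairs passed: CO2 and blue-light signalling (0.898) and jasmonate (0.988), highest in light replicate 2, auxin (0.848), lowest in light replicate 1, and light signalling (0.911) and starch (0.941), lowest in ambient CO2 replicates 4 and 2. Also passing were abscisic acid core (0.965), highest, and vasculature (0.858), lowest, in high CO2 replicate 1, and nitrate assimilation (0.857), highest in high CO2 replicate 4. Of 12 pairs of array measure and group, 3 passed, all given above for light replicate 4.

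Probes without a locus code belong to no comparison of the report. Of 3883 such probes tested, limma called 1073 in darkness (491 higher, 582 lower, 1487 at an unadjusted p under 0.05), 689 for the difference and 967 between the controls, and 0 in high CO2 (327 at an unadjusted p under 0.05).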

How the results depend on the processing

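The alternatives that left out light replicate 4 with ambient CO2 replicate 3, kept probes without a locus code, kept only bright genes or set darkness against the ambient CO2 control, and for the genes called in both responses those with trend and robust, array weights or only bright genes, were chosen only after the result was seen. The cause was not tested for any change below unless fewer genes, fewer arrays or a stricter threshold make it.

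For darkness, every alternative except the threshold of log2 1 (3670 genes, by construction) stayed within 1.5 times of 11352 calls. Leaving out 1 array gave 10035 to 10764, the replicate block 11063, both arrays left out 11275 and the ambient control 12838. The 7 calls of high CO2 depended on nearly every choice: normexp with quantile normalization gave 207, the series matrix values 81, a signal above background on every array 185, trend and robust 222, array weights 393 and only bright genes 252, while the threshold of log2 1 gave 3. Limma gave 0 with no filter, only the compared groups, the replicate block, an adjusted p under 0.01, both arrays left out or probes without a locus code kept, with 3122 genes at an unadjusted p under 0.05 in the report's setting. Leaving out 1 array gave 0 to 338: 338 without high CO2 replicate 1, which kept all 7, and 0 without high CO2 replicates 2, 3 or 4 or ambient CO2 replicates 1, 2, 3 or 4. Normexp and the series matrix values each kept 4 of the 7. The 3 genes called in both responses became 100 with normexp and quantile normalization, 48 with the series matrix, 96 with a signal above background on every array, 116 with trend and robust, 213 with array weights, 133 with only bright genes and 6 with the mean of all probes, 1 at log2 1, and 0 with no filter, only the compared groups, the replicate block, an adjusted p under 0.01 or both arrays left out. Leaving out 1 array gave 0 to 193, with 193 without high CO2 replicate 1 and 0 without any other of the 15 arrays. The difference went from 8334 to 3355 at log2 1 and 5308 at an adjusted p under 0.01, and lay between 7511 and 8385 without 1 array and at 7751 with the replicate block. The controls went from 5630 to 11361 with array weights, 1456 at log2 1 and 2494 at an adjusted p under 0.01. Without 1 array they gave 3518 (light replicate 3) to 6753, and with the replicate block 5288. Each group filled its own slide, so no slide block was run. Arrays of the same replicate number correlated across genes, after removing group means, at 0.05, 0.18 and 0.32 for dark and light and at 0.09, 0.41, 0.59 and -0.07 for high and ambient CO2. The highest correlations with another number were 0.07, 0.28 and -0.14, and 0.12, 0.30, 0.24 and 0.04. The same number was thus higher only for dark and light replicate 4 and CO2 replicates 2 and 3. The numbers were not taken as pairs, and whether some of them share a batch stays open.

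Gene list calls depended on how correlation between genes was treated. Darkness went from 13 lists to 0 with an estimated correlation, 25 with fry and 6 after quantile normalization (10 to 13 without 1 array). High CO2 went from 11 to 0 with an estimated correlation and 2 with fry (9 to 13). The difference went from 10 to 1 with an estimated correlation and 6 after quantile normalization with or without normexp (9 to 13), and the controls from 13 to 0 with an estimated correlation (9 to 13). In high CO2, ion transport and vasculature ended without ambient CO2 replicate 2 (adjusted p = 0.281 and 0.0511), and both abscisic acid lists and aquaporins without high CO2 replicate 3 (0.108, 0.249 and 0.0694). CO2 and blue-light signalling ended there without ambient CO2 replicates 1 or 2 (0.134 and 0.110) or high CO2 replicates 3 or 4 (0.0694 and 0.109). Between the controls, Calvin cycle, flavonoids and photorespiration ended without ambient CO2 replicate 2 (0.228, 0.104 and 0.104), ion transport and CO2 and blue-light signalling without ambient CO2 replicate 3 (0.0680 and 0.230), jasmonate without light replicate 4 (0.0986) and starch without ambient CO2 replicate 1 (0.110). CO2 and blue-light signalling also ended without light replicates 1, 2 or 3 or ambient CO2 replicate 4, and the Calvin cycle without light replicates 1 or 3 or ambient CO2 replicate 4. Jasmonate also ended without ambient CO2 replicates 1 or 4, starch without light replicate 4 or ambient CO2 replicate 4, and flavonoids without light replicate 4 or ambient CO2 replicate 1. For the difference, the Calvin cycle ended without ambient CO2 replicate 1 (0.0991) and jasmonate without ambient CO2 replicate 3 (0.0738). A signal above background on every array ended, among others, photorespiration and vasculature in darkness (0.0611 each) and Calvin cycle and flavonoids for the difference (0.0703 and 0.105). It added flavonoids in high CO2 (9.1e-04). The mean of all probes ended photorespiration and vasculature in darkness (0.176 and 0.0688) and the Calvin cycle for the difference (0.506). It added light harvesting and the Calvin cycle in high CO2 (0.0190 and 0.00522). The replicate block gave 13 lists in darkness, 12 in high CO2, 8 for the difference and 11 between the controls. It ended CO2 and blue-light signalling in high CO2 (0.0544) and between the controls (0.0507), jasmonate between the controls (0.0658) and for the difference (0.0597) and the Calvin cycle for the difference (0.0567), and added salicylate (0.0363) and heat shock (0.0498) in high CO2.

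The direction of photosynthesis lists turned with the scaling. In darkness the adjusted p with the turned direction was 0.621 after quantile normalization and 0.3871 after normexp for light harvesting, 0.621 and 0.7187 for the Calvin cycle and 0.6979 and 0.8523 for mesophyll markers. For the difference it was 0.9456 and 0.8294, 0.5052 and 0.4477, and 0.8893 and 0.8294. LHCB1.3 turned in darkness to -0.1167, -0.0541 and -0.0155 with quantile normalization, normexp and the series matrix, and ANL2 to -0.0232 with the mean of all probes. Direction and side of the threshold held for 112 of 127 named genes in darkness and 83 of 117 in high CO2. Both held for 10 of 10 for the difference, 9 of 10 between the controls, and 1, 9, 13 and 8 of the 27 lists. Neither count covers every alternative (array weights in none, the ambient control only for lists).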

Other observations

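The genes of glucosinolate synthesis were listed only after some of their values had been seen among the largest falls, while their tests were written before the values of the other members were seen.

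Glucosinolates are sulfur-rich defence compounds whose breakdown enzymes, the myrosinases TGG1 and TGG2, are abundant in guard cells. Of 20 genes for the aliphatic branch (made from methionine) whose values had not been seen, 19 fell in darkness and 0 rose by limma, with a median of -2.5791 (camera adjusted p = 8.516e-14, p = 0.0116 with an estimated correlation). The regulator genes MYB28, MYB29 and MYB76 fell by 1.36 (SE 0.11), 3.02 (SE 0.24) and 3.94 (SE 0.18), and CYP79F2, CYP83A1 and SOT17, of the core pathway, had changes of -3.78 (SE 0.22), -2.35 (SE 0.16) and -3.58 (SE 0.17). The transporter gene BAT5 fell by 3.91 (SE 0.24), and IMD3 stood at 0.05 (adjusted p = 0.757). With the 5 members seen before, 24 of 25 fell. The indole branch (made from tryptophan) was mixed: of 11 unseen genes 7 fell and 2 rose, with a median of -1.1571 (camera p = 0.01349, p = 0.0811 with an estimated correlation). With MYB51, seen before and higher by 1.21 (SE 0.24), 7 of 12 fell and 3 rose, and the call ended (camera p = 0.0503, p = 0.172 with an estimated correlation). CYP79B2 and CYP83B1 fell by 1.83 (SE 0.17) and 1.52 (SE 0.23), and CYP81F2 and IGMT1, which modify the indole ring, rose by 2.44 (SE 0.28) and 1.13 (SE 0.20).

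As a hypothesis, darkness may lower the aliphatic branch as a whole, for which the unseen median of -2.5791 was the test. The unseen members were measured on the same arrays as the falls that prompted the list. This test is therefore not independent of those falls. Whether the indole branch falls as a whole stays open, since its call rests on leaving out MYB51. In high CO2 the aliphatic members had a median of 0.1012, with 0 of 20 called by limma (also 0 adjusted over the list alone). As a list, the 11 unseen indole members lay higher there, with a median of 0.2195 (camera p = 3.9e-04, p = 0.0187 with an estimated correlation, both unadjusted), against a median of -1.1571 in darkness. In high CO2, 0 were called by limma and 1 was higher adjusted over the list alone, and GSTF9 stood at -0.0088. Between the controls 10 of 20 aliphatic members were higher at ambient CO2, with a median of 0.3835 (13 adjusted over the list alone). Slide and darkness cannot be told apart for these genes either.

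Among the 56 genes that part the experiments, 18 were above background on no array of the dimmer one, all 56 were called between the controls, 15 in darkness and 0 in high CO2. They include QQS, a species-specific gene of starch regulation, HSD2 and HSD3, neighbouring genes for hydroxysteroid dehydrogenases, and the transporter gene ABCB15.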
